A study of Mus musculus with 2 samples.

How the data were processed

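Total RNA from 2 cultures of mouse embryonic fibroblasts, labelled as given no agent or Fgf2, was analysed on 1 Illumina expression bead array per culture. Per the labels' protocols, 300 ng of RNA was amplified into biotinylated cRNA, so each array has 1 colour. Groups were taken from the agent labels. The design text describes both cultures as lacking Fgf2, which contradicts the titles and agents, so the direction of each difference rests on those labels.

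The deposited table of signals holds, per the file headers, 1 signal and 1 detection value per probe and array. The signals are intensity values on a linear scale, deposited by the authors without normalization between arrays as far as the values show, from about 94 up to 44248 without Fgf2 and 41959 with it. The detection columns hold a p-value per probe, per the file headers, and each falls as the signal column before it rises. The authors also deposited a table of processed values, which the values show to be on a log2 scale: each column has a rank correlation of 1 with the signals of its own array, a slope of about 1.05 on the log2 signal among probes over 5000, and the same median, 4.30, on both arrays. The ranks tie each column to its own array, while the background correction behind it is not given in the sources used here. BeadStudio 3.2, RMA and lumi are named in the submitters' processing notes, with no roles. Whether BeadStudio subtracted a background is not stated. An intensity on these arrays includes a background, estimated here at 127.9 and 128.4, which compresses differences of dim probes unless it is removed.

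Signals were corrected with limma 3.58.1 in R 4.3.3. The mean and SD of the background were inferred from the detection p-values, normexp correction was applied, an offset of 16 added, and the arrays were quantile normalized and put on the log2 scale. A probe counted as detected at a detection p below 0.01. Further steps used Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots matplotlib 3.10.9. The platform annotation gave 23978 probes 1 gene symbol, 0 several and 1719 none. Of the named probes 23962 were found in a RefSeq gene table by Entrez number, which updated their symbols, and the other 16 kept theirs. This gave 16593 genes, of which 4777 had more than 1 probe. A gene was represented by its probe with the highest mean level, chosen without regard to the difference. Probes without a gene name stayed out of all gene counts. No coordinates are given, since no genome build is named in the sources used here.

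With 1 array per group there are no residual degrees of freedom, so no test across samples was run, and counts are of genes at least 2-fold apart among those detected on both arrays. A gene detected on 1 array has only a bound, taken against the lowest normalized level among detected probes of the dim array (5.87 without Fgf2 and 5.99 with it) or the gene's own level there if higher. A list's median was set against 10000 random lists of the same size, matched on deciles of mean level. Its bootstrap SD, from 2000 draws of its members, describes the members and not the cultures. The number of arrays limits the precision. The pooled SD between probes of one gene was 0.26, 0.22 and 0.17 for genes of low, middle and high level, and can include real differences between transcripts.

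The steps were tested on simulated arrays of 25697 probes with noise of SD 0.15 on the log2 scale. Among spiked probes detected on both simulated arrays, at least 2-fold in the right direction were 3 of 50 at a true fold of 1.5, 45 of 47 at 3, 49 of 49 at 4 and 43 of 43 at 8. Of 10498 unchanged probes, 3 passed 2-fold. The simulation held no variation between cultures, so this is not the rate of false calls expected between 2 real cultures.

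Named genes follow a rule fixed before the data were examined: the 15 highest and 15 lowest differences, the 5 greatest bounds in each direction, up to 4 members of each list with the greatest absolute difference, and a fixed set of FGF signalling, reprogramming, cell cycle, matrix and sex-linked genes. Other genes are said to have been chosen after their values were seen. Of that fixed set, Ddx3y had no probe named here. The alternatives tried were other background corrections, offsets of 50 and 1, median scaling and cyclic loess, the authors' processed table, other detection filters, the mean of a gene's probes, thresholds of 1.5-fold and 3-fold, the mean of a list's members, and random lists without matching. Added after the data were seen were list members at their bound, lists without shared members, genes with a detection p of 0 on both arrays, and list percentiles recomputed within each setting.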

Results

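Gene expression was measured in cultured mouse embryonic fibroblasts, primary connective tissue cells from the embryo, grown without or with fibroblast growth factor 2 (Fgf2), a secreted growth factor that acts through receptor tyrosine kinases. The title of the series ties the cultures to a protocol that uses a growth factor in making induced pluripotent stem cells, and the comparison asks how the fibroblasts differ with Fgf2. Each group held 1 Illumina bead array, so no value below has a replicate or a p-value. The labels give neither the dose of Fgf2 nor the duration of exposure. The design text describes both cultures as lacking Fgf2, whereas the titles and agent labels name 1 of them as treated. The grouping followed the agent labels. Of 25697 probes, 10564 (41.1%) were detected without Fgf2 and 10262 (39.9%) with it, and the median probe signals were 149.3 and 148.5. All differences below are Fgf2 minus no Fgf2 on the log2 scale.

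With Fgf2, fibroblasts showed lower levels of collagen, contractile and amino acid response genes, and slightly higher levels of DNA replication and mitosis genes. Among the 6898 genes detected on both arrays, 124 were at least 2-fold higher with Fgf2 and 174 at least 2-fold lower, while 6600 lay within 2-fold. The differences passed 4-fold for 17 genes on the higher side and 28 on the lower side. Levels on the 2 arrays correlated across genes with a Pearson r of 0.969 and a Spearman rho of 0.964, where genes are not independent replicates. The median difference of all these genes was 0.03. Different probes of one gene gave differences with a pooled SD of 0.22 (1749 genes with 4102 probes), which covers measurement error within this pair of arrays and not the spread between cultures. A further detected probe existed for 52 of the genes that were at least 2-fold apart, and in 52 of these every further probe differed in the same direction. The count of higher genes was 53, and of lower genes 96, when no background was subtracted.

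**Figure D1:**
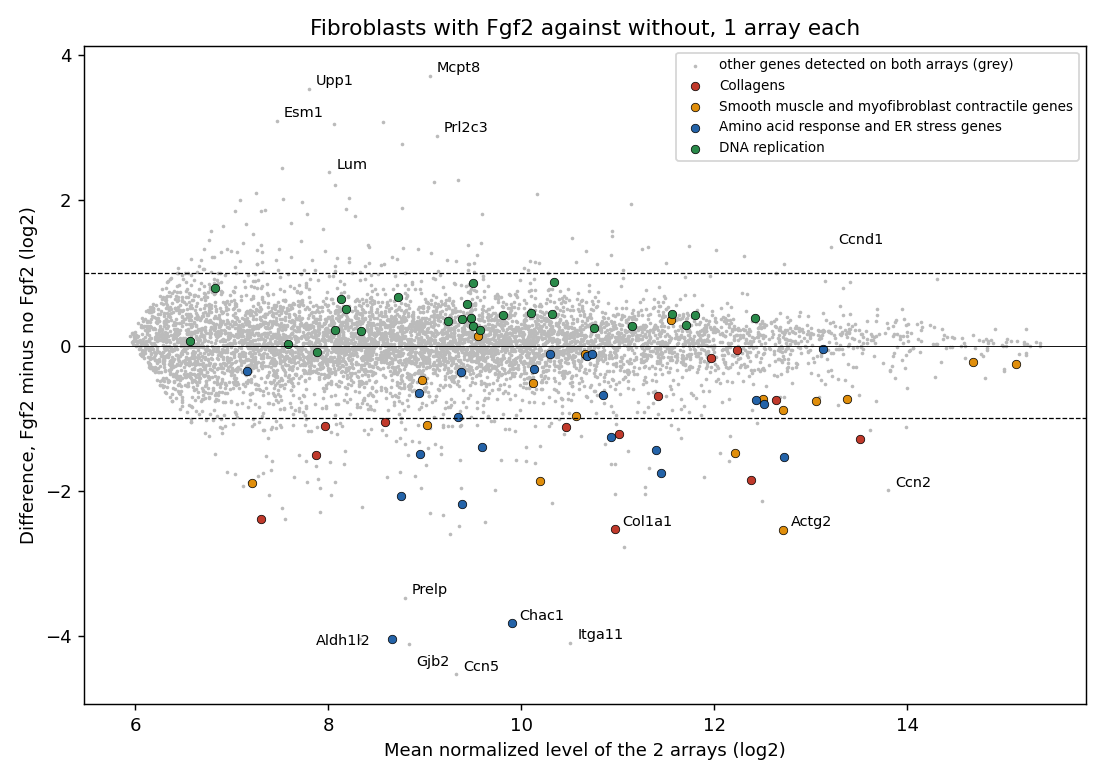
Difference between the arrays (Fgf2 minus no Fgf2, log2) against the mean normalized level of both (log2) for each of the 6898 genes detected on both arrays, with dashed lines at 2-fold. Members of 4 gene lists are coloured: collagens, contractile genes and amino acid response genes lie mostly below 0, and DNA replication genes lie a little above it.

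The gene with the greatest positive difference among those detected on both arrays was Mcpt8, a granule serine protease gene, at 13.1-fold higher with Fgf2. Upp1, which encodes uridine phosphorylase, was 11.6-fold higher, and Esm1, the secreted proteoglycan endocan, 8.53-fold higher. Prl2c4 and Prl2c3, members of the prolactin family, were 8.42-fold and 7.40-fold higher. These paralogs are close copies, so their probes may each read more than 1 of them. Spink2 (8.33-fold), Mgst2 (6.88-fold), Evi2a (5.45-fold), Lum (5.23-fold), Gap43 (4.85-fold), Gch1 (4.78-fold), Btbd11 (4.63-fold), Gdf10 (4.28-fold), Nrn1 (4.25-fold) and Arhgap22 (4.09-fold) completed the 15 highest. Further probes of Upp1 gave smaller differences, 2.96 and 1.785 against 3.54, and neither was detected without Fgf2. Upp1 and Esm1 were barely above background without Fgf2, with detection p-values of 0.0050 and 0.0088. Folds depended on the background correction, and not only for such dim genes, since Mcpt8 had a detection p of 0 on both arrays. Without the correction Mcpt8 was 7.45-fold, Upp1 4.57-fold and Esm1 3.41-fold higher.

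The greatest negative difference belonged to Ccn5, a matricellular protein gene also known as Wisp2, which was 23.0-fold lower with Fgf2. The gap junction gene Gjb2 was 17.2-fold lower and Itga11, a collagen-binding integrin subunit, 17.0-fold lower. The mitochondrial folate enzyme gene Aldh1l2 and the secreted protein gene C1qtnf3 were both 16.5-fold lower, and Chac1, which degrades glutathione, was 14.1-fold lower. Prelp, a leucine-rich matrix proteoglycan, was 11.1-fold lower. Ptx3, which encodes a secreted pentraxin, differed by -2.58. Nupr1 (6.80-fold), Actg2 (5.78-fold), Col1a1 (5.76-fold), Fam20a (5.56-fold), Ccdc80 (5.39-fold), Col5a2 (5.23-fold) and Prss23 (5.21-fold) completed the 15 lowest. The probes of Fam20a gave unequal sizes, with differences of -2.48 and -1.41. C1qtnf3, Col5a2 and Prss23 were barely above background with Fgf2, with detection p-values of 0.0038, 0.0063 and 0.0025. Without background correction Ccn5 was 12.2-fold lower.

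**Figure D2:**
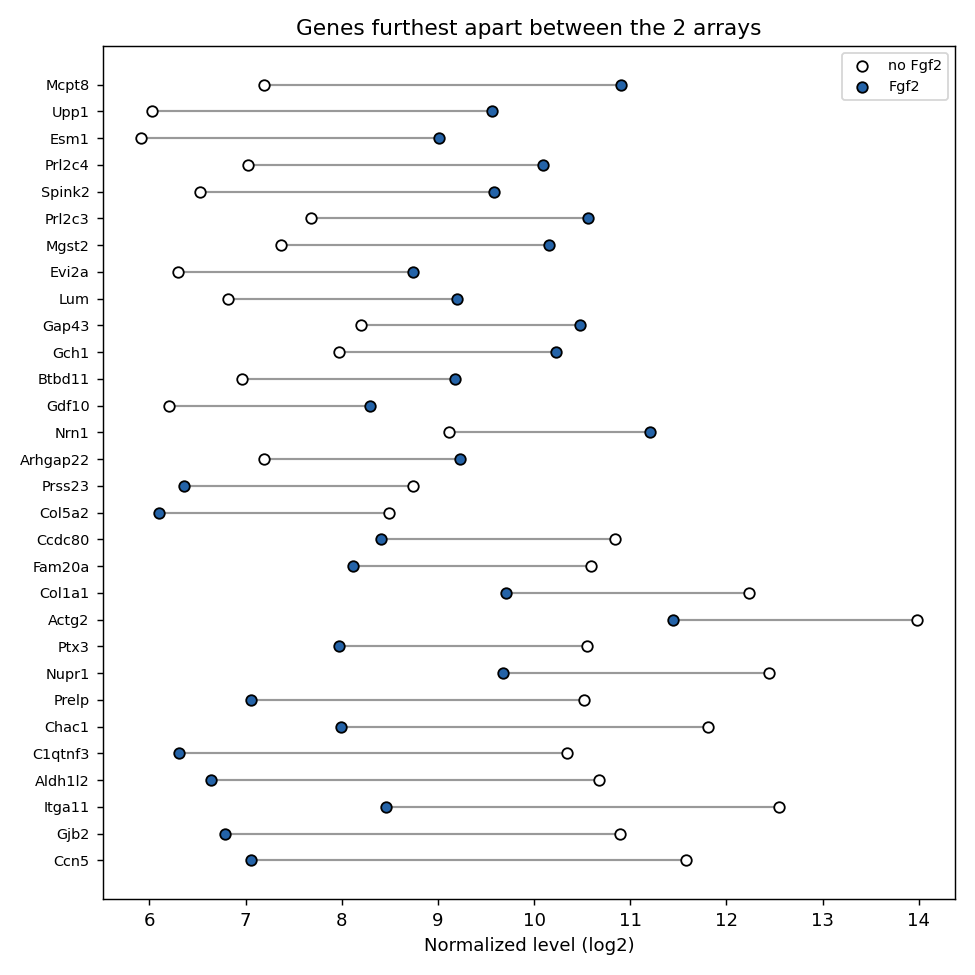
Normalized level (log2) without Fgf2 (open circles) and with Fgf2 (filled circles) of the 15 genes with the greatest positive and the 15 with the most negative difference among genes detected on both arrays; each circle is 1 array. The differences run from 3.71 for Mcpt8 to -4.52 for Ccn5.

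A further 279 genes were detected only with Fgf2 and 472 only without it, and for these the fold is a lower bound against the dimmest detected probe of the other array. Mmp3, the matrix protease stromelysin, was at least 36.3-fold higher with Fgf2, or at least 12.0-fold without background correction. Clu, the extracellular chaperone clusterin, was at least 13.3-fold higher, Inmt at least 12.1-fold, the urea transporter gene Slc14a1 at least 7.40-fold and the protease inhibitor gene Serpina3n at least 5.81-fold. In the other direction, Slc7a3, a transporter of cationic amino acids, was at least 11.9-fold lower with Fgf2. Cdsn was at least 6.94-fold lower, the G protein regulator Rgs4 at least 6.36-fold, the keratin gene Krt14 at least 5.86-fold and Hey1, a Notch target, at least 5.82-fold. The bound reached 2-fold for 31 of the genes detected only with Fgf2 and 38 of those detected only without it.

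Of 35 gene lists fixed before the data were examined, 34 had at least 3 members detected on both arrays. The median differences of 14 of these lay outside the central 95% of 10000 random lists matched on level, 4 above and 10 below, where about 1.7 would by chance. These percentiles describe this pair of arrays, and lists share some members. The figure of 1.7 holds for lists of unrelated genes, whereas members of one list may vary together. With random lists rebuilt under each of 14 other settings that left a list at least 3 members, a check added after the data were seen, 10 of the 14 lists stayed outside throughout and 4 did not: the FGF and ERK, insulin-like growth factor, angiogenic, and chondrocyte and bone lists.

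**Figure D3:**
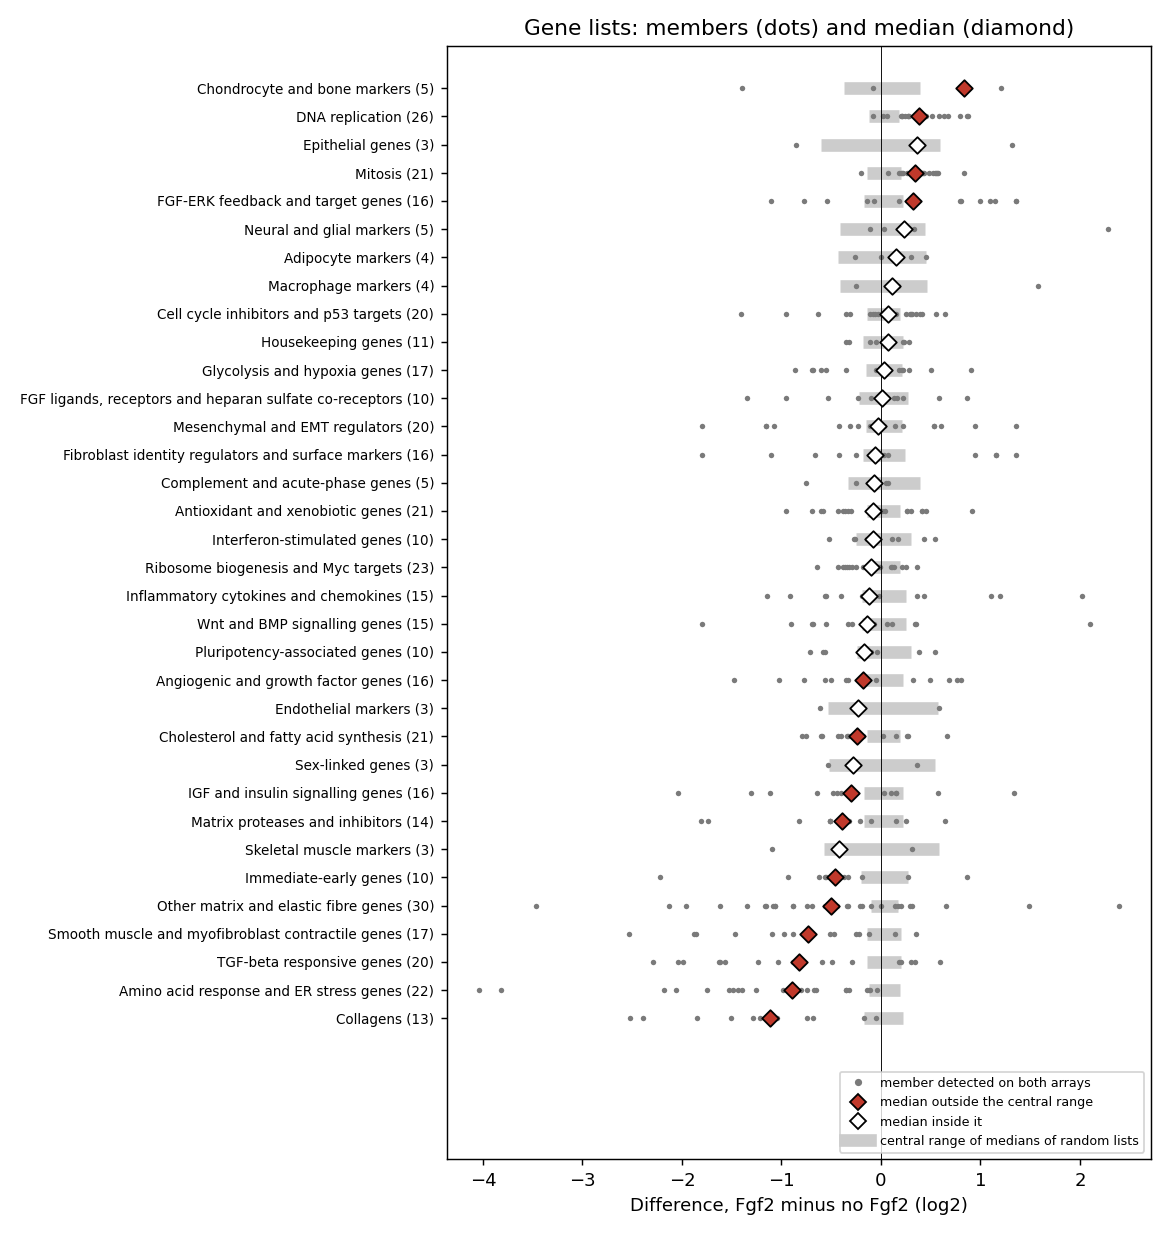
Differences (Fgf2 minus no Fgf2, log2) of the members of each gene list detected on both arrays (dots, their number in brackets) and their median (diamond, filled where it lies outside the central range of medians of matched random lists, shown as a grey bar). Collagens have the lowest median, -1.12, and the list of chondrocyte and bone markers, with 5 members, the highest, 0.83.

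Collagen genes had the lowest median of all lists, -1.12 (bootstrap SD 0.20, 13 genes), which was below every random list. All 13 had a difference below 0, and 9 were at least 2-fold lower with Fgf2. Col1a1 and Col1a2, the chains of type I collagen, were 5.76-fold and 3.61-fold lower. Col5a2 was 5.23-fold lower and Col4a5, of basement membranes, 2.85-fold lower. Among 30 other matrix genes the median was -0.50 (bootstrap SD 0.23), with 10 at least 2-fold lower and 2 higher. The collagen cross-linking enzyme genes Lox and Loxl2 were 4.38-fold and 3.90-fold lower, and the proteoglycan gene Prelp was 11.1-fold lower. Lum, another proteoglycan of the same family, went the other way at 5.23-fold higher.

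Matrix proteases and their inhibitors had a median of -0.39 (bootstrap SD 0.12, 14 genes), at percentile 0.02 of random lists, and 2 were at least 2-fold lower. The inhibitor gene Timp3 was 3.50-fold lower and the aggrecanase gene Adamts5 3.33-fold lower, while the collagenase gene Mmp13 was 1.57-fold higher by its brightest probe and its other detected probe gave -0.05. The bounded Mmp3 is a member of this list. With members detected on 1 array entered at their bound, a choice made after the data were seen, the median was -0.33. Without background correction it was -0.24.

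Genes of smooth muscle and myofibroblast contraction had a median of -0.73 (bootstrap SD 0.19, 17 genes), below every random list, with 15 of 17 below 0 and 5 at least 2-fold lower. Actg2, smooth muscle gamma-actin, was 5.78-fold lower, Lmod1 3.69-fold, Tagln, which encodes transgelin, 3.62-fold and Csrp1 2.77-fold. The brightest probe of Acta2, the myofibroblast marker alpha smooth muscle actin, differed by -0.25, whereas its other 3 probes differed by -1.87 ± 0.12 (SD, n = 3 probes). The gene therefore stands among those within 2-fold, although most of its probes were lower by more.

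TGF-beta responsive genes had a median of -0.82 (bootstrap SD 0.23, 20 genes), below every random list, and 8 were at least 2-fold lower. The ligand gene Tgfb2 was 4.88-fold lower. Ccn4 and Ccn2, which encode matricellular proteins, were 4.12-fold and 3.98-fold lower, and Inhba, the activin subunit, 3.09-fold lower. In the list of insulin-like growth factor signalling genes the median was -0.30 (bootstrap SD 0.15, 16 genes), with 3 at least 2-fold lower and 1 higher. Its percentile was 0.15, and 5.69 among genes above the median level. Its binding protein genes diverged: Igfbp5, Igfbp3 and Igfbp7 were 4.12-fold, 2.48-fold and 2.16-fold lower, and Igfbp4 was 2.52-fold higher.

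Genes of the amino acid response and endoplasmic reticulum stress had a median of -0.89 (bootstrap SD 0.29, 22 genes), below every random list. All 22 had a difference below 0, and 10 were at least 2-fold lower with Fgf2. After Aldh1l2 and Chac1, at 16.5-fold and 14.1-fold lower, came Ddit3, the stress transcription factor CHOP, at 4.53-fold and Mthfd2, an enzyme of mitochondrial folate metabolism, at 4.18-fold. Genes of cholesterol and fatty acid synthesis had a smaller shift, with a median of -0.24 (bootstrap SD 0.05, 21 genes), 16 below 0 and none at least 2-fold apart. In that list Hsd17b7 and Cyp51 were 1.73-fold and 1.69-fold lower, and Elovl6 was 1.58-fold higher.

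DNA replication genes had a median of 0.38 (bootstrap SD 0.05, 26 genes), above every random list. The shift was small and broad: 25 of 26 were above 0 and none reached 2-fold. Tk1, which encodes thymidine kinase, was 1.84-fold higher, the ligase gene Lig1 1.82-fold by its brightest probe, the polymerase gene Pole 1.73-fold and the replication licensing gene Cdc6 1.59-fold. The 3 detected probes of Lig1 ranged from 0.16 to 0.86. Mitosis genes had a median of 0.34 (bootstrap SD 0.06, 21 genes), with 20 of 21 above 0, and included the condensin gene Ncaph at 1.78-fold and Cdk1, the mitotic kinase, at 1.49-fold higher. Cell cycle inhibitors and p53 targets had a median of 0.07 (20 genes), inside the random range, but with the mean of probes the median was 0.20, outside it at percentile 98.4. Cdkn2a was 1.56-fold higher and Cdkn1a differed by -0.11, each by its brightest probe, and Gadd45a was 2.65-fold lower. The 3 detected probes of Cdkn1a ranged from -0.57 to -0.11, and the 2 of Cdkn2a from 0.64 to 0.93.

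Targets and feedback genes of FGF and ERK signalling had a median of 0.32 (bootstrap SD 0.27, 16 genes), at percentile 99.87 of random lists, with 4 at least 2-fold higher and 1 lower. Without a detection filter the percentile was 96.7, inside the range. Hmga2 and the cyclin gene Ccnd1 were both about 2.6-fold higher, with differences of 1.36, and the 3 probes of Ccnd1 ranged from 1.29 to 1.69. Spred1, an inhibitor of the pathway, was 2.21-fold higher, the transcription factor gene Etv4 2.14-fold, and Dusp6, the ERK phosphatase, 1.75-fold. Etv5 missed the 2-fold mark narrowly, with a difference of 0.997. Plaur, the urokinase receptor gene, was 2.15-fold lower. Spry4 was detected only without Fgf2, with a bound of 1.17-fold, and Spry2 on neither array.

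Immediate-early genes had a median of -0.46 (bootstrap SD 0.16, 10 genes), at percentile 0.04. With no detection filter the median was -0.20 over 20 genes, at percentile 0.69. Egr2 was 4.66-fold lower and the phosphatase gene Dusp1 1.91-fold lower, while Jun was 1.82-fold higher. Angiogenic and growth factor genes had a median of -0.18 (bootstrap SD 0.17, 16 genes), at percentile 2.08, and lay inside the random range under 7 of the 14 other settings. In that list Ptn, which encodes pleiotrophin, was 2.78-fold lower. The list of chondrocyte and bone markers had a median of 0.83 (bootstrap SD 0.63) over only 5 detected genes, of 22 on the array. Sox5 was 2.31-fold higher and Sox9 1.78-fold higher, but the cartilage collagen gene Col2a1 was 2.64-fold lower, and over all 22 genes without a detection filter the median was -0.02, inside the random range at percentile 36.8.

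The other 20 lists lay inside the random range in the main analysis, and 6 of them left it under at least 1 other setting. FGF ligands, receptors and co-receptors had a median of 0.01 over 10 genes, and 4 more were detected only without Fgf2. Over genes detected on at least one array the median was -0.33, below the range at percentile 0.78. Wnt and BMP signalling genes had a median of -0.14 at percentile 6.32, and lay below the range under 3 settings. Among 10 detected pluripotency-associated genes the median was -0.17 and none was 2-fold apart. Pou5f1, Sox2 and Nanog, core pluripotency factors, were detected on neither array, and Klf4 differed by -0.20. Myc was detected only without Fgf2, with a bound of 1.56-fold. With Fgf2 its detection p was 0.010025, just above the threshold of 0.01. The transcript of Fgf2 itself was below detection on both arrays, with detection p-values of 0.16 and 0.15. That of its receptor Fgfr1 missed the threshold of 0.01 on both arrays, with 0.014 without Fgf2 and 0.038 with it. Mesenchymal and EMT regulators had a median of -0.03 (20 genes) with members on both sides: the receptor gene Pdgfrb was 3.48-fold lower and Pdgfra 2.56-fold higher. Inflammatory cytokines and chemokines had a median of -0.12 (15 genes), with Ptges, a prostaglandin E synthase gene, 4.06-fold higher and Ptgs2, cyclooxygenase 2, 2.22-fold lower. Housekeeping genes had a median of 0.07 (11 genes).

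Markers of other cell types were mostly below detection. Of 18 macrophage markers on the array 4 were detected on both arrays, with Cd14 2.99-fold higher and Lyz2 differing by 0.17. Cd14 was barely above background without Fgf2, with a detection p of 0.0088. Another 2 macrophage markers were detected only without Fgf2 and 0 only with it. Detected on both arrays were 3 of 16 endothelial, 3 of 17 skeletal muscle, 4 of 14 adipocyte and 3 of 25 epithelial genes, with medians of -0.23, -0.42, 0.15 and 0.36. A further 4 epithelial genes were detected only without Fgf2 and 0 only with it. Over genes detected on at least one array, the epithelial percentile went from 87.8 to 25.9 and the endothelial from 16.8 to 63.2. So these few genes give no firm direction. None of 9 haemoglobin and erythroid genes was detected. The neural list had 5 detected genes and a median of 0.23, with Gap43 4.85-fold higher. Both cultures are labelled male. The Y-linked genes Eif2s3y and Uty were detected on both arrays, with differences of -0.28 and -0.54, and Kdm5d on neither. Xist, expressed from the inactive X chromosome and normally silent in male cells, was also detected on both arrays, which conflicts with the label. Its probes differed by 0.36 and 0.16, so Xist was higher and the 2 detected Y-linked genes lower on the array with Fgf2, each by less than 2-fold. Whether the cultures differed in their mix of sexes was not tested.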

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

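Most tests below were chosen after the results were seen; the test of transfer RNA synthetases and the statement on the number of arrays for the collagens were set before.

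Probes without a gene name entered none of the comparisons. Of the 554 detected on both arrays, 11 were at least 2-fold higher on the array with Fgf2 and 16 at least 2-fold lower. The highest, ILMN_1238547, was higher by 3.40 on the log2 scale, and the lowest, ILMN_1225528, differed by -4.24.

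The collagen median was low on the array with Fgf2. The way the signals were scaled was argued against, since the highest collagen median over 7 other background corrections, offsets, scalings and the authors' table was -0.97, still below the random range. The mesenchymal list did not fall with the collagens: its median was -0.027, above theirs by 1.09, more than the SD of its members, 0.76. Of its 20 genes, 4 were at least 2-fold lower and 1 higher. These values argue against a replacement of mesenchymal cells by other cells as the whole account, since that would lower both lists. They cannot show a loss of cells. With 300 ng of RNA per array and quantile normalization, such a loss could leave this median near 0. A changed mix of fibroblast types was not tested, since it could leave this median near 0. Any other difference between the 2 cultures, such as density, passage or the mix of sexes, cannot be told apart from Fgf2, because the number of arrays per group was 1. An effect of Fgf2 on matrix genes stays open as a hypothesis, untested by replication.

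Amino acid response genes were low on the same array. Scaling was argued against, with a highest median of -0.80 over the same 7 settings. The 7 detected chaperones of the endoplasmic reticulum had a median of -0.14 (bootstrap SD 0.11), and 13 amino acid response genes had -1.49. Differences of these chaperones ran from -0.66 for Pdia6 to -0.04 for Hsp90b1. The chaperones thus fell less than the amino acid response genes, but this comparison was chosen after the values of the list were seen. It does not decide whether the unfolded protein response was lower, since chaperones cover only a part of that response. A lower programme of the transcription factor ATF4 may account for the pattern: 10 cytosolic transfer RNA synthetases known as its targets, none of them in the list, were all lower with a median of -0.87, against 0.17 for 5 other synthetases, a contrast of -1.04 (bootstrap SD 0.17). Another difference between the 2 cultures, for example how far the medium was used up, cannot be told apart from Fgf2 with arrays per group at 1.

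The brightest Acta2 probe differed by -0.25 and its other 3 probes by -2.001 to -1.77. Clipping or a loss of response near the top of the scale stays open: the bright probe's signal was 88.4% of the highest on the array without Fgf2, its brighter array, and 78.5% of the highest on the other, and both signals were known before the test was chosen. Cross-hybridization with other actin transcripts could also hold this probe up: it lay 0.24 above the median of 3 Actb probes, -0.49, which neither excludes nor singles out that explanation. An isoform difference was not tested.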

How the results depend on the processing

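Detection p of 0, lists without shared members, list members at their bound and percentiles within each setting were chosen after the data were seen. No paired analysis was possible because each group has 1 array. Against main counts of 124 higher and 174 lower, the counts were 53 and 96 without background correction, 219 and 279 for genes detected on at least one array, 236 and 286 with no detection filter, and 42 and 85 for genes above the median level. At 1.5-fold they were 466 and 500, and at 3-fold 31 and 63. Only the higher count moved by over 1.5 times under normexp on the signals with offset 50 (70) and a detection p of 0 on both arrays (81). The other 16 counts stayed within 1.5 times. The lower share of genes apart ran from 51.8% at 1.5-fold to 67.0% at 3-fold, against 58.4%. The cause of these moves was not tested, beyond the thresholds and filters that change which genes enter.

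Of the medians of the 14 lists outside the random range, 204 of 209 moved by less than their bootstrap SD. The exceptions were immediate-early genes with no detection filter (-0.20), matrix proteases without background correction (-0.24), amino acid response genes as the mean of members (-1.19), IGF genes above the median level (-0.15), and chondrocyte and bone markers with no detection filter, which reversed to -0.020; there 17 undetected genes enter. With random lists not matched on level, all 34 lists stayed on their side of the range. With random lists rebuilt within each of 14 settings, 10 of the 14 lists outside stayed there and 4 entered the range. FGF and ERK genes did so with no detection filter (percentile 96.7), IGF genes above the median level (5.69), and chondrocyte and bone markers with no detection filter (36.8) and as the mean of members (90.6). Angiogenic genes did so with median scaling (2.69), cyclic loess (2.98), no detection filter (4.73), genes above the median level (4.75), the mean of probes (3.15), the mean of members (10.2) and without members of other lists (9.21). Of the 20 lists inside, 6 left the range. FGF ligands and receptors did so with genes detected on at least one array (0.78) and a detection p under 0.05 (1.96), and Wnt and BMP genes with that p (1.45), no detection filter (0.21) and the mean of probes (2.31). Cell cycle inhibitors did so with the mean of probes (98.4), ribosome biogenesis genes with median scaling (2.14) and cyclic loess (2.45), skeletal muscle markers with no detection filter (1.80) and neural markers as the mean of members (98.99). Of the 169 named genes with a value, 87 moved by more than the spread between probes without background correction, 57 under normexp on the signals, 39 at offset 50, 32 in the authors' table, 30 as the mean of probes, 23 at offset 1 and 0 under cyclic loess or median scaling; no called gene reversed. Filters on detection cannot change a gene's own value and are not counted there. Signal over background limits dim genes: the pooled SD between probes was 0.26 for genes of low level and 0.17 for those of high level.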

Other observations

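The genes in this part were chosen after their values were seen, except Slc7a3, Hey1, Gch1 and Gadd45a; the test of Notch genes was set before those genes were looked at.

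Outside the fixed lists, Slc6a9, a glycine transporter, was 4.93-fold lower and Slc1a4, a carrier of neutral amino acids, 3.04-fold lower, beside Slc7a3 at a bound of 11.9-fold, while Slc38a2 differed by -0.12. Atf5, a transcription factor gene related to Atf4, was 3.85-fold lower. Trib3, a pseudokinase gene and a member of the fixed amino acid response list, was detected only without Fgf2, at least 5.03-fold lower with it. The 3 Gadd45 genes, which encode stress and growth arrest proteins, were lower by similar sizes: Gadd45a differed by -1.41, Gadd45b by -1.58 and Gadd45g by -1.59.

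Genes of tetrahydrobiopterin synthesis differed among themselves. Gch1, which encodes the first enzyme of the pathway, was 4.78-fold higher with Fgf2, and Gchfr, its feedback regulator, was detected only with Fgf2, at least 4.30-fold higher. Pts and Spr, which act after it, differed by 0.06 and 0.10. The transcription factor gene Etv1 and the protease gene Mmp10 were detected only with Fgf2, at least 4.01-fold and 5.30-fold higher. The matrix genes Eln and Mfap5, the kinase gene Mylk and the chemokine gene Cxcl14 were detected only without it, at least 2.94-fold, 2.65-fold, 4.71-fold and 4.87-fold lower with Fgf2.

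Hes1 was 2.84-fold lower with Fgf2, and Hey1 and the ligand gene Jag1 were at least 5.82-fold and 5.23-fold lower, which could reflect lower expression of the Notch pathway as a hypothesis. The other 9 Notch pathway genes detected on both arrays had a median of -0.016, at percentile 37.7 of matched random lists, with 6 below 0 and 3 above. A median inside the random range, -0.26 to 0.30, had been set beforehand as evidence against the hypothesis. By that bound these genes, mostly pathway components, argue against lower expression of the pathway as a whole. The bound was judged a poor one after the value was seen, because the members went both ways. Few of the genes were targets, so lower activity of the pathway is left open.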
